A study of Mus musculus with 46 samples.

How the data were processed

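T cell receptor beta (TCRβ) rearrangements of sorted mouse T cells were analysed. Per the labels, DNA was isolated with a kit that yields DNA and RNA, and rearrangements were amplified by PCR with primers for all mouse V and J segments. The labels list 46 samples, of which 17 libraries were analysed and 29 were not analysed here. The deposited tables list, for each CDR3 nucleotide sequence, its read number in counts, with no normalization. The deposited tables also give each rearrangement's fraction of reads, and this fraction equalled the count divided by the table's own total. The authors' processing notes name genome build mm10, and they state neither the program that assigned the segments nor its version. All listed rearrangements were in frame and 0 held a stop codon, so the tables hold productive rearrangements only. Between 0.903% and 1.59% of the rearrangements per library had a CDR3 that did not run from cysteine to phenylalanine or tryptophan, and these were kept. Segment positions were taken from an annotation of GRCm38.p6, which is the same build as mm10.

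Library totals ranged from 278420 to 571124 reads over 1698 to 19898 rearrangements. Between 15.3% and 53.9% of the rearrangements of a library had 1 read. A count of 0 allows 3 reads, which is 0.000525% to 0.00108% of the reads of a library. Wilson 95% confidence intervals are given for shares of single libraries. The reads come from PCR without molecular identifiers, so intervals and floors cover counting error only. The number of cells behind each library is unknown. Shares of top clonotypes and clonotype numbers at equal reads may therefore also reflect cell number.

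A clonotype was a V segment with a CDR3 amino acid sequence. Reads were summed per V and per J segment, and segments with a mean of at least 10 reads were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, quasi-likelihood test, two-sided). V and J segments were fitted apart and adjusted together by the Benjamini-Hochberg method at 0.05. CNS and periphery libraries were compared with no covariate. Regulatory T cells (Treg) and conventional T cells (Tcon) were compared with the 4 combinations of immunization and gestational state as a term. Pregnant mice at embryonic day 18 (E18) and non-pregnant mice were compared with cell type and immunization as terms. Immunized and naive mice were compared with cell type and gestational state as terms. Several groups held 1 library, which was assumed to vary like the other groups. Clonotype abundance in the CNS and the periphery was tested in the same way for clonotypes seen in at least 3 of the 6 libraries. DESeq2 1.42.0 with its own size factors was the other tool. P-values from replicates measure only the spread between samples.

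Single values per library were compared by exact two-sided permutation tests within strata. These values were the share of reads in the 10 most abundant clonotypes, the number of clonotypes after thinning to 278420 reads (mean of 20 draws), the mean CDR3 length with each clonotype counted once, and the share of reads in CNS-enriched clonotypes. The last set held clonotypes seen in at least 2 CNS libraries with a mean share there at least 2 times that in the periphery. CNS against periphery allows 20 assignments and a smallest p of 0.1. Treg against Tcon and E18 against non-pregnant each allow 24 assignments and a smallest p of 0.0417. In the permutations 7 Treg stood against 3 Tcon libraries, because the naive E18 Tcon library had no Treg counterpart. The fitted changes between Treg and Tcon also rest on 3 Tcon libraries, since the term for naive E18 takes up its only library. EAE against naive allows 8 assignments and a smallest p of 0.25. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

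The tests, the alternatives, the segment lists and the rule for named items were fixed before the data were examined. The rule named all segments past the threshold, TRBV13-1, TRBV13-2, TRBV13-3, TRBV16, TRBV12-1 and TRBV12-2, the top clonotype of each library, the 10 clonotypes with the largest mean share in CNS among those seen in at least 2 CNS libraries, the 10 largest fold changes among called clonotypes, and the 5 CNS-enriched clonotypes with the largest mean share in Treg of immunized E18 mice. The lists were Vβ8 (TRBV13-1, TRBV13-2, TRBV13-3), Vβ5 (TRBV12-1, TRBV12-2), J cluster 1, J cluster 2, and V segments favoured by natural killer T (NKT) cells (TRBV13-2, TRBV29, TRBV1) as a marker of another cell type that a sort could hold. Segments called only under an alternative (TRBV4, TRBV5, TRBV14, TRBV17, TRBV19, TRBV20, TRBV31, TRBJ1-7, and with 1 library left out TRBV15, TRBV30, TRBJ2-3 and TRBJ2-7), and TRBV1 and TRBJ1-5, were named after their values were seen. TRBV12-1 and TRBV12-2, and the members of TRBV13, are close paralogs, and how reads were divided among them is not stated.

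The alternatives fixed in advance were each clonotype counted once, DESeq2, no TMM, no filter on low segments, at least 2 reads per rearrangement, subsets of the libraries, other definitions of a clonotype, other numbers of top clonotypes, other depths, the replicate number as a block, and leaving out each replicate in turn. Added after seeing the data was a carry-over filter, which left out of a library each rearrangement whose share of reads was under 5% of its share in another library. It removed 0.573% to 32.4% of the rearrangements and 0.0937% to 1.30% of the reads of a library. The combinations of that filter, of the block and of leaving out replicates with each clonotype counted once were also added then.

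Same-numbered CNS and periphery libraries were checked for pairing by correlating, across the 36 segments, each library's deviations of log2 share from its group mean; segments are not independent replicates. By reads r was 0.371, 0.672 and 0.120 for replicates 1, 2 and 3, and by rearrangements 0.360, 0.721 and 0.653. Different-numbered libraries gave -0.687 to 0.531 by reads, where CNS 3 with periphery 1 was above the same-numbered pairs 1 and 3, and -0.634 to 0.310 by rearrangements. All 6 same-numbered values were above 0.1, which does not establish that same numbers are pairs. The blocked values, which take the numbers as pairs, are given beside the segment results. These correlations were computed after the calls of the blocked fit had been seen. Sharing of identical rearrangements pointed to other pairs, and the closing section gives it.

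The library codes have a part shared by all Tcon libraries, another by all Treg libraries and another by all wild-type libraries, followed by a number. They were read here as run and position, which no source states.

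The tests were run on simulated data with the dispersions of these libraries. With 6 V segments changed 8-fold, the test by reads called 76.7% (CNS against periphery), 84.2% (Treg against Tcon), 90.0% (E18) and 84.2% (EAE) of them. With a change of 2-fold it called 1.67% to 6.67%. With each clonotype counted once, a change of 2-fold was called in 90.0%, 98.3%, 97.5% and 98.3%. The test of clonotype abundance, with 200 of 660 clonotypes changed 16-fold, called 0% at the estimated dispersion (median 7.59) and 99.5% at a preset dispersion of 0.2. On simulated libraries the carry-over filter removed 92.1% of the carried-over rearrangements and kept 97.8% of the public ones. Carry-over was simulated at a fixed rate far under the filter's limit of 5%, so a high removal was largely set in advance. The 92.1% does not apply to carry-over at higher ratios. The public ones were drawn with the same range of sizes in both simulated libraries. The simulation therefore does not show how many truly shared clones of unequal size the filter removes.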

Results

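TCRβ rearrangements were sequenced from T cells of mice with experimental autoimmune encephalomyelitis (EAE), an animal model of multiple sclerosis, and of naive mice. The series title concerns pregnancy and the expansion of autoreactive regulatory T cells. CD8-negative T cells came from the central nervous system (CNS, n = 3) and the periphery (n = 3) of non-pregnant wild-type C57BL/6 mice with EAE. Treg and Tcon came from spleen and lymph nodes of DEREG mice, a transgenic line that marks Foxp3-expressing cells. Treg of EAE mice at E18 formed 1 group of 5 libraries. The groups with 1 library each were Treg of non-pregnant EAE mice, Treg of non-pregnant naive mice, and Tcon of EAE E18, EAE non-pregnant, naive E18 and naive non-pregnant mice. Treg of naive E18 mice were not analysed here. Library totals ranged from 278420 to 571124 reads.

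A few large clonotypes dominated the reads of CNS libraries, and not those of periphery libraries. The 10 most abundant clonotypes held 31.0% ± 9.2 of the reads in CNS libraries (SD, n = 3, range 25.2% to 41.6%) and 2.00% ± 0.56 in the periphery (SD, n = 3, range 1.41% to 2.51%). The largest CNS clone, TRBV13-2 with CDR3 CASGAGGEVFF, took 15.4% of the reads of CNS replicate 1 (Wilson 95% interval 15.3% to 15.6%). TRBV19 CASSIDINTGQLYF led CNS replicate 2 with 5.44% (5.37% to 5.52%) and TRBV13-2 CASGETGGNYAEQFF led CNS replicate 3 with 4.01% (3.94% to 4.07%). The top clonotypes of the periphery, TRBV13-2 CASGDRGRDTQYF, TRBV16 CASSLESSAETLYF and TRBV31 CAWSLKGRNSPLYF, held 0.205%, 0.292% and 0.358%. At 278420 reads, CNS libraries held 2116 ± 629.9 clonotypes (SD, n = 3) and periphery libraries 7997 ± 3549 (SD, n = 3). CNS libraries had 111 to 198 reads per rearrangement and periphery libraries 24.8 to 64.3. Fewer cells in CNS samples could raise the share and lower the clonotype number, and the closing section leaves this open. The shares and the clonotype numbers of the groups did not overlap, and each gave p = 0.1 in an exact two-sided permutation test (n = 3 against 3), which is the smallest p this design allows. Mean CDR3 length was 13.98 ± 0.084 amino acids in CNS and 13.92 ± 0.041 in the periphery (SD, n = 3 each), with p = 0.4 in the exact two-sided permutation test, and weighted by reads the difference was -0.00282. With at least 2 reads per rearrangement it was 0.145 (exact permutation p = 0.1). Without periphery replicate 1 the difference in clonotypes shrank from -5881 to -3877, and the difference in CDR3 length was 0.0966 without CNS replicate 2 and 0.0123 without CNS replicate 3.

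**Figure D1:**
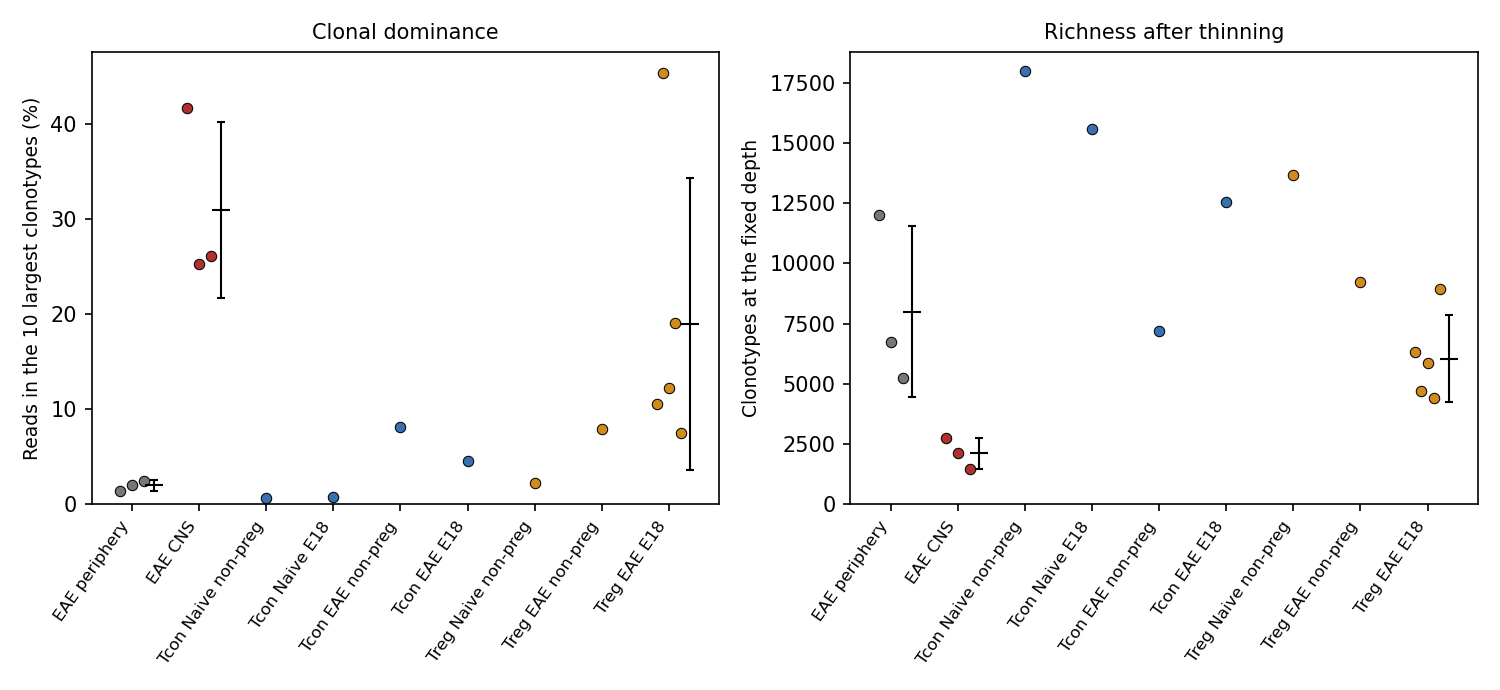
Share of reads in the 10 most abundant clonotypes (percent) and number of clonotypes at 278420 reads for each group. Dots are libraries and horizontal lines with whiskers are mean and SD where a group has more than 1 library. The 3 CNS libraries sit at 25.2% to 41.6% and the 3 periphery libraries at 1.41% to 2.51%.

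V segment usage also differed between CNS and periphery when each clonotype was counted once, but the calls did not hold with the carry-over filter. TRBV5 (Vβ1) made up 10.1% ± 0.95 of CNS clonotypes and 7.25% ± 0.79 of periphery clonotypes (SD, n = 3 each), with a fitted log2 change of 0.68 (SE 0.13, edgeR adjusted p = 0.0203). Fitted changes include TMM normalization and so differ from the ratios of the percentages. No fit with each clonotype counted once was run without TMM. TRBV20 (Vβ15) made up 6.17% ± 0.64 against 4.37% ± 0.54, a log2 change of 0.70 (SE 0.16, edgeR adjusted p = 0.0325). TRBV17 (Vβ9) was lower, with 0.758% ± 0.037 against 1.33% ± 0.086 and a log2 change of -0.63 (SE 0.16, edgeR adjusted p = 0.0432). For each of these segments the 3 CNS libraries lay on 1 side of the 3 periphery libraries. TRBV13-2 (Vβ8.2), which many T cells specific for myelin oligodendrocyte glycoprotein use in this strain, made up 20.7% ± 5.1 of CNS and 15.0% ± 0.69 of periphery clonotypes, with a log2 change of 0.69 (SE 0.22, edgeR adjusted p = 0.0695). Its adjusted p over the Vβ8 list alone was 0.0368. The Vβ8 list as a whole held 27.9% ± 4.2 of CNS and 21.8% ± 0.61 of periphery clonotypes (exact two-sided permutation p = 0.1, the smallest possible). The 3 calls were lost with the carry-over filter, which left 0, and without CNS replicate 3 or periphery replicate 1, each of which left 0. That filter removed 16.1% to 32.4% of the rearrangements of CNS libraries and 4.24% to 6.21% of those of periphery libraries. Counted once, a carried-over rearrangement of 1 read weighs as much as a large clone. Without CNS replicate 1 or periphery replicate 2 only TRBV5 was called, and without CNS replicate 2 TRBV13-2 took the place of TRBV17 among 3 calls. Over the 9 settings with each clonotype counted once the log2 changes stayed at 0.58 to 0.77 for TRBV5, 0.54 to 0.79 for TRBV20 and -0.68 to -0.54 for TRBV17.

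Weighted by reads, edgeR called 0 of 36 segments between CNS and periphery, with 4 at an unadjusted p under 0.05, and DESeq2 called 0. TRBV20 had a log2 change of 1.53 (SE 0.59), TRBV5 of 1.25 (SE 0.56) and TRBV13-2 of 1.16 (SE 0.52), each with adjusted p = 0.371 in edgeR. Without CNS replicate 2 TRBV20 was the 1 call (log2 change 1.98, adjusted p = 0.0404). TRBV13-3 had a log2 change of 1.62 (SE 1.05, adjusted p = 0.564), and TRBV13-1 of -0.04 (SE 0.57), TRBV16 (Vβ11) of 0.10 (SE 0.51), TRBV12-1 of -0.67 (SE 0.69) and TRBV12-2 of 0.22 (SE 2.04) had larger adjusted p-values. Vβ8 held 35.5% ± 9.0 of CNS reads and 24.4% ± 5.3 of periphery reads, and the NKT-favoured list held 36.6% ± 6.4 and 29.8% ± 0.95 (SD, n = 3 each). Both gave p = 0.2 in exact two-sided permutation tests. J cluster 1 held 36.5% ± 14.4 of CNS reads and 30.6% ± 1.7 of periphery reads, and J cluster 2 held the rest (exact permutation p = 0.6), while with each clonotype counted once CNS was lower in J cluster 1 by a difference of -1.22 percentage points.

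With the replicate number as a block, TRBJ1-7 was lower in CNS by reads, with a log2 change of -1.85 (SE 0.27, edgeR adjusted p = 0.00124) at 0.00486% ± 0.0038 of CNS and 0.0172% ± 0.011 of periphery reads. Its log2 change was 0.07 (SE 0.86) by clonotypes without a block. With each clonotype counted once the block gave 5 calls, adding TRBV14 (log2 change -0.60, SE 0.13) and TRBV4 (-0.33, SE 0.09) to TRBV5, TRBV20 and TRBV17. The block takes the replicate numbers as pairs, although by reads CNS replicate 3 correlated more with periphery replicate 1 (r = 0.531) than with periphery replicate 3 (r = 0.120) across the 36 segments. Identical rearrangements, described in the closing section, also linked libraries of different numbers more than those of the same number. The blocked calls therefore rest on a doubtful pairing.

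Most abundant CNS clonotypes were large in a single library. The 10 with the largest mean share were led by TRBV13-2 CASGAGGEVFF (5.15% ± 8.9 of CNS reads, SD, n = 3), TRBV2 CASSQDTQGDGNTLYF (2.62% ± 4.5) and TRBV13-2 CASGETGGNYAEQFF (2.42% ± 1.9). The other 7 were TRBV19 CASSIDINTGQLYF, TRBV26 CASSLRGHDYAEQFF, TRBV13-2 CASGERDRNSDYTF, TRBV20 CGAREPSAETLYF, TRBV15 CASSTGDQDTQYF, TRBV20 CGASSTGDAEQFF and TRBV20 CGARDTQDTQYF, with means from 1.83% down to 0.958%. TRBV20 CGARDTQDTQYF was an exception, with 0.416% and 2.46% of the reads of CNS replicates 2 and 3, and was not found in CNS replicate 1. TRBV13-2 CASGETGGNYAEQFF was another: it held 0.302%, 2.94% and 4.01% of the reads of CNS replicates 1, 2 and 3, and 0.0423% ± 0.062 of periphery reads (SD, n = 3). Its CNS reads came from 8 different CDR3 nucleotide sequences after the carry-over filter, of which 2 were common to all 3 CNS libraries. It was found in 4 of the 5 Treg libraries of EAE E18 mice at a mean of 0.0877% ± 0.13 (SD, n = 5), and in 3 of them after the filter. It was not particular to them: it was found in 8 DEREG libraries, among them Tcon of the E18 (0.0544%) and the non-pregnant (0.0191%) EAE mouse. Before the filter 109 clonotypes were seen in all 3 CNS libraries, and after it 4, namely this one and TRBV5 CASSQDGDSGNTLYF, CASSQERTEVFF and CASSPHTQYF. The edgeR test of 660 clonotypes called 0, with 35 at an unadjusted p under 0.05, and DESeq2, which gave a p-value for 211 of the 660, called 65, of which 3 were higher and 62 lower in CNS, with log2 changes from -12.77 to 20.65. A log2 change of 20.65 is larger than the read totals can show, so it is not a measured fold. On simulated data the edgeR test called 0% of clonotypes changed 16-fold at this spread.

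**Figure D2:**
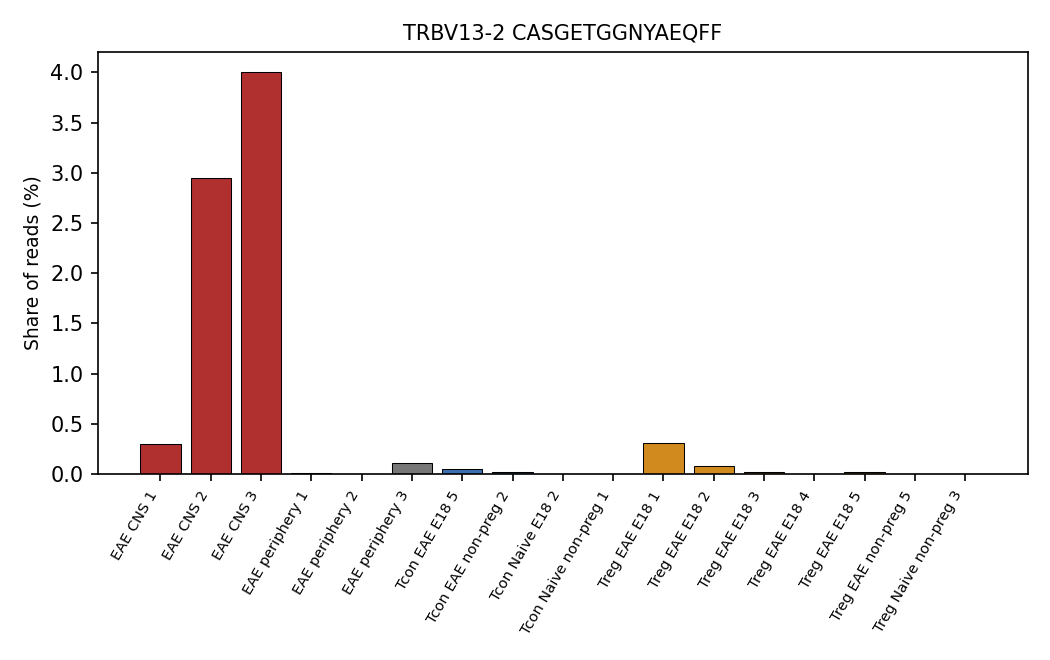
Percent of reads of the clonotype TRBV13-2 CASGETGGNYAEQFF in each of the 17 libraries, 1 bar per library. CNS replicates 2 and 3 stand at 2.94% and 4.01%.

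Treg used TRBV12-1 (Vβ5.2) more than Tcon, and TRBV31, TRBV4 and TRBV19 less, when each clonotype was counted once. TRBV12-1 made up 4.48% ± 1.1 of Treg clonotypes (SD, n = 7, range 3.15% to 6.55%) and 1.06% ± 0.080 of Tcon clonotypes (SD, n = 4, range 0.967% to 1.15%). The log2 change was 2.11 (SE 0.25, edgeR adjusted p = 0.000195), and all 7 Treg libraries lay above all 4 Tcon libraries. The fitted changes rest on 3 Tcon libraries, each the only one of its condition, because the naive E18 one had no Treg counterpart. CNS and periphery libraries, which were not sorted on Foxp3, held 2.15% ± 0.26 and 2.77% ± 0.77 (SD, n = 3 each). TRBV31 (Vβ14) was lower in Treg, with 6.44% ± 0.57 against 8.89% ± 0.60 and a log2 change of -0.44 (SE 0.08, edgeR adjusted p = 0.00338). TRBV4 (Vβ10) was lower with 3.70% ± 0.46 against 4.81% ± 0.31 (log2 change -0.48, SE 0.10, edgeR adjusted p = 0.0113), and TRBV19 (Vβ6) with 7.47% ± 0.51 against 8.50% ± 0.48 (log2 change -0.29, SE 0.07, edgeR adjusted p = 0.0121). TRBV13-2 made up 13.7% ± 1.7 of Treg and 13.9% ± 1.6 of Tcon clonotypes (log2 change -0.11, SE 0.14).

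Weighted by reads, TRBV12-1 held 2.37% ± 1.1 of Treg reads (SD, n = 7) and 0.714% ± 0.24 of Tcon reads (SD, n = 4), a log2 change of 1.99 (SE 0.48, edgeR adjusted p = 0.0679). It passed when adjusted over the Vβ5 list alone (adjusted p = 0.00377), with DESeq2 (log2 change 2.05, SE 0.50, adjusted p = 0.00125), and without Treg EAE E18 replicate 2 (log2 change 2.16, adjusted p = 0.00709). It did not pass in edgeR without TMM or without the non-pregnant EAE Tcon library, where the smallest adjusted p of any segment was 0.227 and 0.654. Its log2 change stayed at 1.79 to 2.33 over all 31 settings, by reads or by clonotypes. edgeR called 0 of 36 segments by reads, with 1 at an unadjusted p under 0.05, and DESeq2 called 1. TRBV12-2 had a log2 change of 1.80 (SE 2.13), TRBV16 of -0.00 (SE 0.40), TRBV13-1 of -0.09 (SE 0.41), TRBV13-2 of -0.08 (SE 0.45) and TRBV13-3 of -0.32 (SE 0.88), none with an adjusted p under 0.05. With each clonotype counted once, TRBV12-1 was called in 13 of 13 settings, with adjusted p from 1.0e-07 to 0.00309. TRBV31 and TRBV4 were called in 11 of them and TRBV19 in 7, and TRBV19 was lost without Treg EAE E18 replicate 1, 2, 4 or 5 or either naive non-pregnant library (edgeR adjusted p up to 0.0917). TRBV12-1 was the 1 call left of 4 without the naive non-pregnant Tcon library or the naive non-pregnant Treg library, while 7 segments were called without Treg EAE E18 replicate 3, adding TRBV1 (log2 change -0.24), TRBV14 (-0.49) and TRBV15 (0.43). TRBV1 (-0.31) and TRBJ2-7 (0.19) were also called without the EAE E18 Tcon library, TRBV14 (-0.57) and TRBJ2-3 (-0.30) without either non-pregnant EAE library, and TRBV30 without the naive E18 Tcon library (0.71) or Treg EAE E18 replicate 1 (0.77). All Treg libraries carried 1 run code and all Tcon libraries another, so no value within a run can be had, and run and cell type cannot be told apart.

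**Figure D3:**
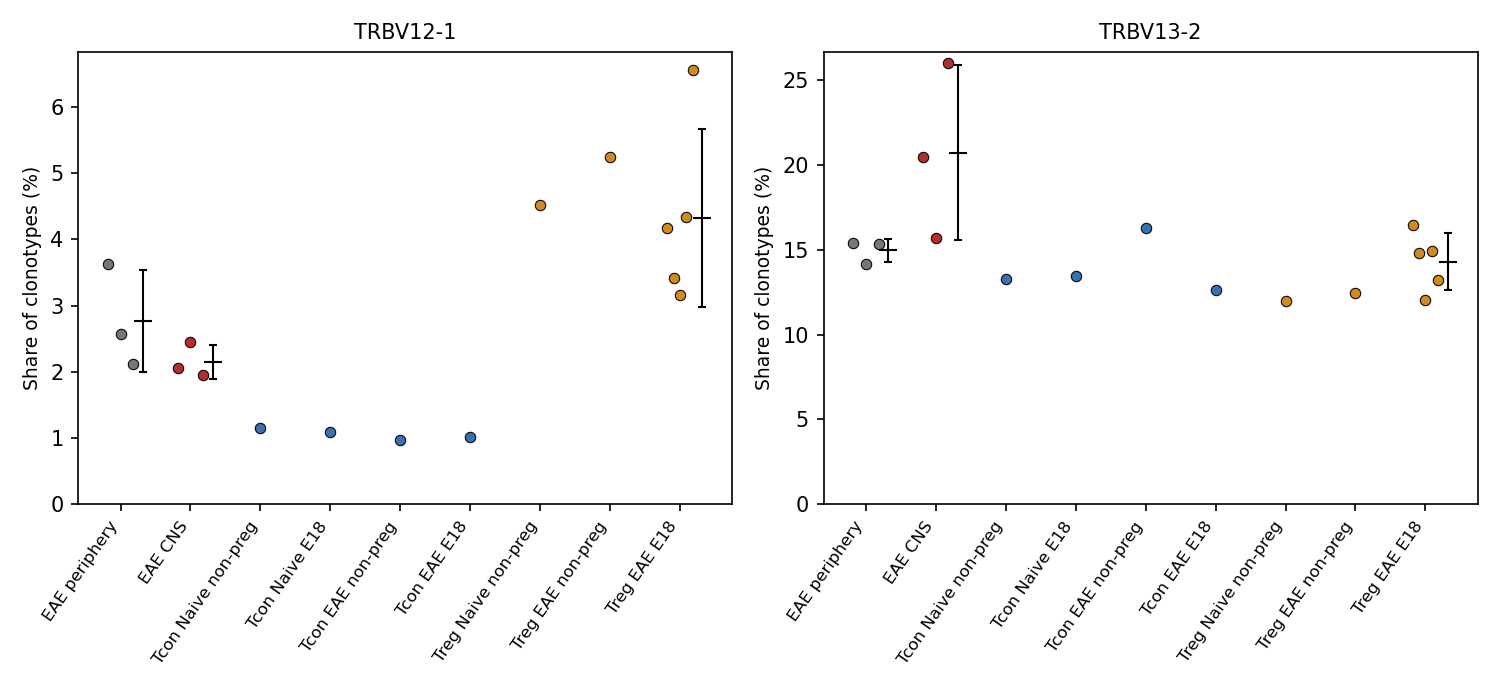
Percent of clonotypes that used TRBV12-1 and TRBV13-2 in each group, with each clonotype counted once. Dots are libraries, with mean and SD where a group has more than 1. The 7 Treg libraries lie at 3.15% to 6.55% for TRBV12-1 and the 4 Tcon libraries at 0.967% to 1.15%.

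Clones in Treg libraries were large in EAE E18 mice, with a wide spread. In the 5 libraries of this group the 10 most abundant clonotypes held 7.47% to 45.4% of reads, and in replicate 2 a single clone, TRBV20 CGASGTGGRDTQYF, held 32.9% (Wilson 95% interval 32.8% to 33.1%). The 10 most abundant held 7.94% in Treg of the non-pregnant EAE mouse and 2.22% in Treg of the naive mouse, 4.54% and 8.18% in Tcon of the E18 and non-pregnant EAE mice, and 0.809% and 0.692% in Tcon of the E18 and non-pregnant naive mice. Within conditions, Treg exceeded Tcon by 5.23 percentage points (p = 0.25) and held fewer clonotypes at fixed depth, a difference of -2920 (p = 0.167; exact two-sided permutation tests, 7 Treg against 3 Tcon). The first difference was 3.03 without Treg EAE E18 replicate 2, 0.642 without the EAE E18 Tcon library and 7.96 without either non-pregnant EAE library. The second was -1127 without the EAE E18 Tcon library and -5396 without either non-pregnant EAE library, a pair in which Treg held more clonotypes (9216 against 7184). Mean CDR3 length was 13.78 ± 0.042 amino acids in Treg (SD, n = 7) and 13.84 ± 0.017 in Tcon (SD, n = 3), a difference within conditions of -0.0499 (p = 0.0833, exact two-sided permutation test). With the carry-over filter the difference was -0.0447 (exact permutation p = 0.0417, the smallest p these permutations can give), weighted by reads it was 0.0151, and without the EAE E18 Tcon library it was -0.0270. Top clonotypes of the other Treg libraries held 0.465% to 4.29% of reads and those of Tcon 0.0969% to 3.57%. They were TRBV13-1 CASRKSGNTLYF, TRBV13-1 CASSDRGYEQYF, TRBV13-2 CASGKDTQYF and TRBV1 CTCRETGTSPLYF in replicates 1, 3, 4 and 5 of EAE E18 Treg, TRBV1 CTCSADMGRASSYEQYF and TRBV4 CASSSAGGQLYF in EAE and naive Treg of non-pregnant mice, and TRBV1 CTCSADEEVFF, TRBV19 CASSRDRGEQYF, TRBV13-2 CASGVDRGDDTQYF and TRBV1 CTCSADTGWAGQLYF in Tcon of EAE E18, EAE non-pregnant, naive E18 and naive non-pregnant mice.

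Pregnancy at E18 came with no called change in V segment usage. TRBV13-2 held 20.6% ± 5.3 of E18 reads (SD, n = 7) and 16.6% ± 5.5 of non-pregnant reads (SD, n = 4), a log2 change of 0.36 (SE 0.36, edgeR adjusted p = 0.774). The labels do not state whether same-numbered Treg and Tcon libraries came from 1 mouse, so n counts libraries and not mice. TRBV12-1 had a log2 change of -0.03 (SE 0.39), TRBV12-2 of -1.11 (SE 2.10), TRBV13-1 of 0.58 (SE 0.35), TRBV13-3 of 0.48 (SE 0.82) and TRBV16 of -0.15 (SE 0.35). edgeR called 0 of 36 segments, with 2 at an unadjusted p under 0.05, and DESeq2 called 0. With each clonotype counted once edgeR called 0 of 34, with 1 at an unadjusted p under 0.05. That segment was TRBJ1-5, with a log2 change of -2.61 (SE 0.70, adjusted p = 0.105), and adjusted over the J cluster 1 list alone its p was 0.0186. Its share of reads was 0.00841% to 0.0217% in 6 of 7 E18 libraries and in the naive non-pregnant Tcon library, and 0.583% to 3.12% in the other 10 libraries. TRBJ1-5 was the 1 call by clonotypes without Treg EAE E18 replicate 1 (log2 change -3.16, adjusted p = 0.00403) or without the naive non-pregnant Tcon library (-2.77, adjusted p = 0.0334), and by reads without Treg EAE E18 replicate 1 (-5.21, adjusted p = 0.00989).

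Clonality and diversity at E18 did not differ from the non-pregnant state in a steady direction. The share of the 10 most abundant clonotypes was 2.49 percentage points higher (p = 0.625), the number of clonotypes at fixed depth differed by -66.0 (p = 0.958) and mean CDR3 length by 0.00266 amino acids (p = 0.958), all in exact two-sided permutation tests of 7 E18 against 3 non-pregnant libraries. Vβ8 held 27.4% ± 4.9 of E18 reads (SD, n = 7) and 23.0% ± 6.2 of non-pregnant reads (SD, n = 3), with an exact permutation p of 0.542. These means join strata that went opposite ways: clonotypes differed by -3173 in EAE Treg, 5366 in EAE Tcon and -2392 in naive Tcon, and the top 10 share by 11.0, -3.64 and 0.116 percentage points, so a mean near 0 does not show that E18 made no difference. Without either EAE Tcon library the differences were 5.56 percentage points, -2782 clonotypes (exact permutation p = 0.0833) and -0.0123 amino acids, without the non-pregnant EAE Treg library -1.76, 1487 and 0.0301, and without either naive Tcon library 1097 clonotypes and -0.00986 amino acids. Without Treg EAE E18 replicate 2 the top 10 share differed by 0.287 percentage points. At 139210 reads the number of clonotypes differed by 93.2, and with each clonotype counted once Vβ8 differed by -0.0661 percentage points.

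Libraries of EAE mice had a higher top 10 share and fewer clonotypes than those of naive mice in all 3 matched pairs. Pairs were matched by cell type and gestational state, with 1 library on each side. Cell numbers are unknown, and thinning to equal reads does not equalize them, so a difference in cell number stays open. The 10 most abundant clonotypes held 6.89% ± 2.0 of EAE reads and 1.24% ± 0.85 of naive reads (SD, n = 3 each), and the clonotypes at fixed depth numbered 9650.1 ± 2709 and 15739 ± 2148. Both differences, 5.65 percentage points and -6089 clonotypes, gave p = 0.25 in exact two-sided permutation tests, the smallest p this design allows. Without either non-pregnant Tcon library the latter was -3743. TRBV13-2 held 20.6% ± 5.7 of EAE reads (SD, n = 8) and 15.4% ± 2.6 of naive reads (SD, n = 3), a log2 change of 0.69 (SE 0.40, edgeR adjusted p = 0.917). TRBV12-1 had a log2 change of -0.54 (SE 0.45), TRBV12-2 of -0.09 (SE 2.60), TRBV13-1 of 0.22 (SE 0.39), TRBV13-3 of 0.47 (SE 0.91) and TRBV16 of -0.07 (SE 0.40). edgeR called 0 of 36 segments, with 1 at an unadjusted p under 0.05, and DESeq2 called 0; with each clonotype counted once edgeR called 0, with 2. Without the Treg library of the non-pregnant EAE mouse edgeR called TRBV19 by reads (log2 change 1.33, adjusted p = 0.0221).

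Across the 4 comparisons and 5 lists, 0 list members were called by reads over all segments and 1, TRBV12-1 in Treg, when adjusted over the list alone. With each clonotype counted once 1 was called over all segments and 5 when adjusted over the list alone. These were TRBV12-1 in Treg against Tcon, TRBV13-2 in CNS against periphery for the Vβ8 and for the NKT-favoured list, TRBV1 in Treg against Tcon, and TRBJ1-5 at E18. Vβ5 held 4.56% ± 1.2 of Treg clonotypes (SD, n = 7) and 1.07% ± 0.12 of Tcon clonotypes (SD, n = 3), with an exact permutation p of 0.0833.

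Clonotypes enriched in the CNS were present at low levels among Treg and Tcon of the spleen and lymph nodes. The set held 895 clonotypes, and its share of reads ranged from 0.344% to 3.97% in DEREG libraries and was 1.44% ± 0.49 in the wild-type periphery (SD, n = 3). The rule that chose the set holds the periphery value down, so that value is not an independent baseline for the DEREG libraries. Treg of EAE E18 mice held 0.400% to 3.97% and Treg of the non-pregnant EAE mouse 0.344%. The planned background was 694 clonotypes enriched in the periphery over the CNS by the same rule. They held 0.954% to 4.98% and 1.22% in the same Treg groups, so these levels were not particular to CNS-enriched clonotypes. The members of the CNS-enriched set with the largest mean share in Treg of EAE E18 mice were TRBV13-2 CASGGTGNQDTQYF (0.705% ± 1.2, SD, n = 5), TRBV16 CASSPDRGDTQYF (0.130% ± 0.29), TRBV13-2 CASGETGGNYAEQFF (0.0877% ± 0.13), TRBV13-2 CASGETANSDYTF (0.0782% ± 0.12) and TRBV13-2 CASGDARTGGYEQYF (0.0612% ± 0.12). The first of these held 2.86% of Treg EAE E18 replicate 4, but only 0.000269% and 0.00178% of CNS replicates 2 and 3. It was not found in CNS replicate 1. After the carry-over filter it, TRBV16 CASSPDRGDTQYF and TRBV13-2 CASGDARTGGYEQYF each remained in 1 CNS library, short of the 2 that the set requires. In the share of the CNS-enriched set, Treg differed from Tcon by -0.215 percentage points (p = 0.875), E18 from non-pregnant by 0.0199 (p = 0.875) and EAE from naive by 0.611 (p = 0.5), in exact two-sided permutation tests with 3 libraries in the smaller arm. None of these was steady when 1 library was left out. The Treg difference ranged from -0.752 (without the EAE E18 Tcon library) to 0.488 (without either non-pregnant EAE library), the E18 difference from -0.599 (without the non-pregnant EAE Treg library) to 0.641 (without either EAE Tcon library), and the EAE difference from 0.114 (without either non-pregnant Tcon library) to 0.982 (without either non-pregnant Treg library). With the carry-over filter the set held 122 clonotypes, the mean share fell from 1.26% to 0.261% in Treg (n = 7) and from 1.02% to 0.334% in Tcon (n = 3), EAE differed from naive by 0.189 percentage points, and E18 differed from non-pregnant by -0.162 percentage points.

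Identical rearrangements were shared between libraries of different mice and strains. Of the top 1000 rearrangements of each EAE E18 Treg library, 168, 141, 147, 109 and 0 were found in the wild-type library with the same position code. In the 25 other pairs of these libraries the median was 5 and the highest 119, which was Treg EAE E18 replicate 5 in periphery replicate 2. Among all pairs of libraries, the number of the top 100 rearrangements found, in the direction with more, had a median of 39.5 in the 8 pairs with the same position code, 12.5 in the 42 pairs with the same run code (highest 98) and 2 in the 86 others, so sharing was not limited to the position code. Low shares of a clonotype in any library carry this limit.

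**Figure D4:**
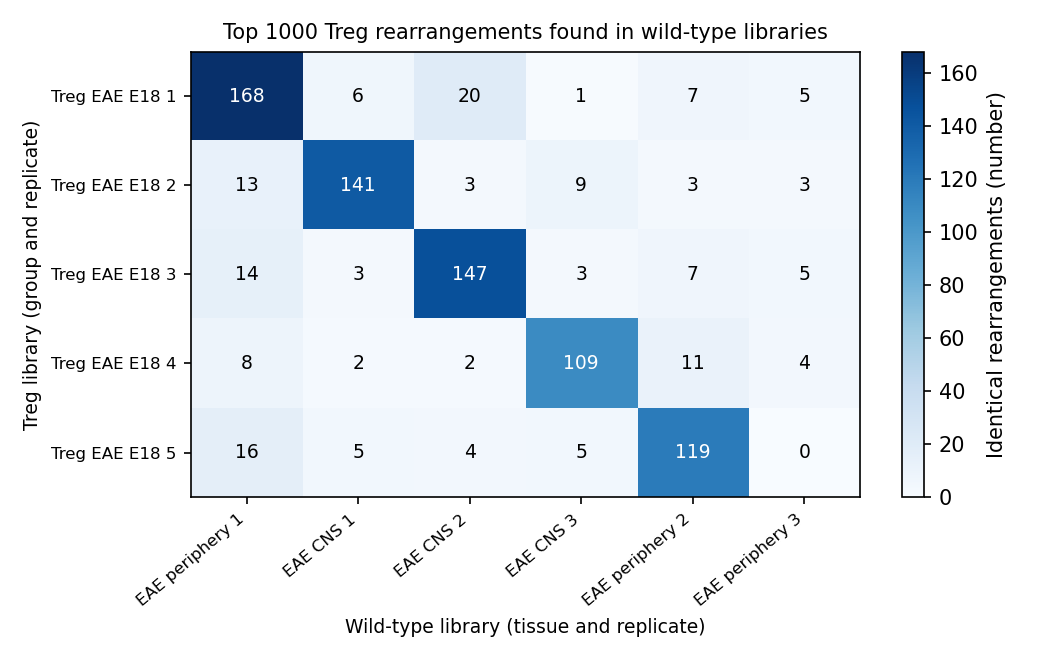
Number of the top 1000 rearrangements of each of the 5 EAE E18 Treg libraries (vertical axis) found in each of the 6 wild-type libraries (horizontal axis). The pairs with the same position code reach 168, and the other pairs have a median of 5.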

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

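The tests of TRBJ1-5 below were chosen after its values were seen. In the only group with 4 to 10 libraries, Treg of EAE E18 mice (n = 5), 23 quantities were tested for a library far from the others, and 7 had such a library. The quantities overlap, shares of reads depend on each other, and some segments were named after their values were seen. No chance rate is therefore given. TRBV20 held 47.8% of the reads of replicate 2 and 2.61% to 4.14% of the others, and TRBV16 held 1.25% of replicate 2 and 6.82% to 7.94% of the others. The TRBV20 clone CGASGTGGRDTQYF accounted for 32.9% of the reads of that library. In replicate 3, TRBV5 held 8.94% of reads (1.39% to 2.87% in the others), TRBV17 held 0.748% (0.0879% to 0.227%) and TRBV12-2 held 0.0393% (0% to 0.00722%). Clonotypes enriched in the wild-type periphery held 4.98% of the reads of replicate 4 and 0.954% to 2.08% of the others. TRBJ1-5 held 0.718% of the reads of replicate 1 and 0.00841% to 0.0217% of the others.

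TRBJ1-5 was nearly absent from 7 libraries and present in the other 10, at 0.583% to 3.12% of reads. Of the 7 low libraries, 6 were E18 and 1 was non-pregnant. Pregnancy as the whole cause is argued against by 2 DEREG libraries out of place at a limit of 0.1% of reads, Treg EAE E18 replicate 1 and the naive non-pregnant Tcon library, and the run code by the 2 run codes that held libraries on both sides. A loss of the whole J cluster is argued against by the neighbour TRBJ1-6, whose lowest share in the low libraries was 4.87% (other libraries 2.12% to 7.94%). A difference between mice or in the J primers of single reactions may remain, and neither was tested.

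For 10 of the 23 quantities, all 5 EAE E18 Treg libraries lay on 1 side of the non-pregnant EAE Treg library, and EAE Tcon (1 against 1) differed in the opposite direction. These differences between cell types were not tested. Means alone had opposite signs in further quantities that did not meet this rule, such as the top 10 share (11.0 in Treg and -3.64 in Tcon) and Vβ5 (-1.07 and 0.246 percentage points). The 10 overlap, since the J clusters sum to 100% and TRBV13-2 is part of Vβ8, and each rests on the same 3 single libraries. Treg at E18 differed by 1.26 percentage points in CNS-enriched clonotypes and Tcon by -1.22. Periphery-enriched clonotypes, which are not among the 10, differed by 1.01 and 0.147. The CNS-enriched values come from the set of 895 clonotypes before the carry-over filter, and with the filter the set held 122. In Treg EAE E18 replicate 4 the set held 3.97% of reads, of which TRBV13-2 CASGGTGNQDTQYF alone held 2.86%. After the filter that clonotype remained in 1 CNS library, short of the 2 the set requires. For Vβ8 the differences in Treg and Tcon were 9.85 and -7.37 percentage points, and for TRBV13-2 8.2 and -8.94. For J cluster 1 they were 4.49 and -0.923, and for J cluster 2 -4.49 and 0.923. For TRBV16 they were -3.16 and 1.71, for TRBV17 -1.38 and 0.530, and for TRBV31 -1.77 and 1.96 percentage points. The number of clonotypes at fixed depth differed by -3173 in Treg and 5366 in Tcon, and mean CDR3 length by -0.0523 and 0.0326 amino acids.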

How the results depend on the processing

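The settings chosen after the data were seen included the carry-over filter and the combinations with each clonotype counted once. They also included leaving out replicates for the shares of single CNS clonotypes. Most other settings were fixed in advance. Of 110 values of the comparisons under other settings, 87 kept their direction and side of the threshold or moved by less than the spread between libraries, 7 passed the threshold newly, 1 no longer passed, 4 moved by more than the spread, 10 reversed their sign and 1 with no test that could pass changed sign within the spread. With 1 library left out, 206 of 241 were kept and 20 reversed. For single segments, clonotypes and lists, 250 of 311 kept their direction and side of the threshold, or moved by less than the spread, under other settings and 684 of 863 with 1 library left out; 42 and 132 changed sign, none of them called in either setting.

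Segment usage by reads gave 0 calls in each comparison. With each clonotype counted once it gave 3 for CNS against periphery and 4 for Treg against Tcon, and DESeq2 gave 1 for Treg against Tcon. Reads add the sizes of single clones to the spread (median dispersion 0.291 by reads and 0.0125 by clonotypes for CNS against periphery). With the replicate number as a block, CNS against periphery gave 1 call by reads and 5 by clonotypes, and with the carry-over filter 0 by clonotypes; the block changed no other call. With 1 library left out, the calls by reads ranged from 0 to 1 in each comparison, and by clonotypes from 0 to 4 for CNS against periphery, 1 to 7 for Treg against Tcon and 0 to 1 for E18. DESeq2 called 65 clonotypes in CNS against periphery, where edgeR called 0. The cause was not tested for these changes of tool, block, filter and library.

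The difference in the share of top clonotypes, CNS minus periphery, was 8.01 percentage points for the top 1 and 55.2 for the top 100, by the construction of the measure. None of the reversed values passed the threshold. Weighted by reads, mean CDR3 length differed by 0.0151 between Treg and Tcon and by -0.0654 between E18 and non-pregnant, and with at least 2 reads by -0.00714 for E18. The number of clonotypes at E18 differed by 227.4 with at least 2 reads and by 93.2 at 139210 reads. The share of CNS-enriched clonotypes at E18 differed by -0.0158 (seen in all 3 CNS libraries), -0.0343 (at least 5 times the periphery share), -0.0679 (CDR3 without V segment), -0.190 (at least 2 reads) and -0.162 (carry-over filter). With 1 library left out, the E18 differences ranged from -1.76 to 5.56 (top 10 share), -2782 to 1487 (clonotypes), -0.0123 to 0.0301 (CDR3 length) and -0.599 to 0.641 (CNS-enriched share), and the Treg difference in CNS-enriched share from -0.752 to 0.488. Mean CDR3 length differed by 0.145 between CNS and periphery with at least 2 reads (exact permutation p = 0.1, the smallest possible) and by 0.137 with the carry-over filter, and between Treg and Tcon by -0.0447 with that filter; the cause was not tested. The number of clonotypes in EAE against naive ranged from -7621 to -3743 with 1 library left out.

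All rearrangements in place of productive ones could not be run, since the tables list productive ones only. Depth limits rare clonotypes: up to 53.9% of the rearrangements of a library had 1 read, and a count of 0 allows up to 0.00108% of reads.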

Other observations

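The tests of carry-over, depth, inserted bases, cell number and other splits of the libraries were chosen after the results were seen. After the carry-over filter, few of the most abundant clonotypes were shared between CNS libraries. Among the top 500 clonotypes left by the filter, pairs of CNS libraries shared 9.33 ± 5.1 (SD, 3 pairs) and pairs of periphery libraries 6.0 ± 1.7. Of these, 6.0 ± 3.5 and 3.0 ± 1.0 had no nucleotide sequence in common. The filter removes rearrangements that are large in 1 library and small in another, so it partly sets these counts. At low levels the sharing was wide: 98 of the top 100 rearrangements of CNS replicate 3 and 91 of those of CNS replicate 2 were found in CNS replicate 1, at medians of 0.00802 and 0.00443 times their reads. After the carry-over filter, 130 clonotypes were seen in at least 2 CNS libraries, against 954 before it. Treg and Tcon libraries of replicate 5 of EAE E18 mice shared 217 rearrangements after the filter, which held 6.07% of the Treg and 3.72% of the Tcon reads. These libraries had the same position code, the labels do not state whether they came from 1 mouse, and n counts libraries, so it is not known to be the number of mice.

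CNS and periphery libraries shared most rearrangements across replicate numbers. After the filter, CNS replicate 1 shared 120 rearrangements with periphery replicate 2, which held 9.36% of its reads, and CNS replicate 2 shared 129 with periphery replicate 3, which held 10.1%. Same-numbered libraries shared 16, 13 and 7. If the linked libraries came from the same mice, the unblocked tests and splits of CNS against periphery ignored that pairing. No fit with the linked libraries as blocks was run.

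Treg of EAE E18 mice and wild-type libraries shared rearrangements at low levels, though they came from different mice, and carry-over of reads between libraries is a candidate explanation. In 4 of the 5 pairs with the same position code 109 to 168 of the top 1000 were shared and in 1 pair 0 (5 and 7 in the 2 such pairs of a Tcon and a periphery library), and shared rearrangements had a median of 0.417% of the reads they had in the Treg library, and 96.8% of those found had under 5%. Receptors made independently in different mice should have fewer inserted bases, but found minus not found was -0.0095 bases in these pairs (SE of the mean of those found 0.096), which argues against them as the main source. The difference was -0.595 in the other 25 pairs. Without Treg replicate 5 in periphery replicate 2, a pair that stood apart with 119 shared rearrangements, the other pairs gave -0.905. A swap of labels between libraries, which would change the position pairs and the same-numbered pairs of the block, was not tested.

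The large clones of the CNS were weighed against a difference in sequencing depth, carry-over and cell number. The read totals of 0 CNS libraries (336240 to 371512) lay outside the range of the periphery libraries (324273 to 390593), and with the carry-over filter the difference in the top 10 share was 29.2 percentage points, which argues against depth and carry-over. Fewer cells in the CNS samples could raise the share, but periphery libraries drawn down to the mean CNS clonotype number, with each read taken as a cell, gave a top 10 share of 2.46% ± 0.38 (SD, n = 3). Because the cell numbers are unknown and the draw assumes the clone sizes of the periphery, this explanation stays open. Clonal expansion in the inflamed tissue is the biological explanation the design gives, and it was not tested apart from the tissue.

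Segment calls were compared with those of other splits of the same libraries. For Treg against Tcon with each clonotype counted once, 1 of 24 splits gave as many calls, namely the real one with 4, and the highest other gave 1. This is a share of 0.0417, the smallest these splits allow, and taken alone it argues against chance. It does not exclude chance, since this was 1 of 9 sets of splits with no correction, and without either naive non-pregnant library the real count was 1. The run code follows the same split and is not addressed. By reads 24 of 24 splits gave as many as the real 0, with a highest other of 3. For E18 against non-pregnant, 24 of 24 splits gave as many as the real 0 by reads and by clonotypes, and the highest other was 0. For CNS against periphery by clonotypes, 1 of 10 splits gave as many, the real one with 3, and the highest other gave 0. The same-numbered pairs are parted by 4 of the 10 splits, and the 3 of these that are not the real one gave 0. By reads, and in the test of clonotype abundance, 10 of 10 splits gave as many as the real 0, with a highest other of 0. For EAE against naive 8 of 8 splits gave as many as the real 0, by reads and by clonotypes, with a highest other of 0. A count of 0 is met by every split, so these comparisons with a real 0 say nothing about chance. The 10 splits of CNS against periphery and the 8 of EAE against naive are too few for a share under 0.05.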
